A study of Dinoroseobacter shibae DFL 12 = DSM 16493 with 6 samples.

How the data were processed

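The measurements were two-colour Agilent microarray hybridisations of RNA from Dinoroseobacter shibae, a marine bacterium of the Roseobacter group. Wild-type cells, a mutant lacking the AHL synthase gene luxI1 (delta-luxI1), and this mutant given 1 of 3 AHLs at 500 nM were compared. AHLs, or acyl-homoserine lactones, are the signal molecules of one kind of bacterial quorum sensing. The cultures grew in the dark at 30 °C on succinate and were sampled at an OD600 of 0.4, per the labels' protocols. Each of the 6 arrays carried one condition labelled with Cy3 and another with Cy5. The arrays formed a loop, so that wild-type, C18-HSL and C18en-HSL were each hybridised 2 times and delta-luxI1 and C18dien-HSL each 3 times. The dye of each condition came from the labels. The labels state between 2 and 3 biological replicates, which is also the number of hybridisations per condition, but they do not tie a culture to a hybridisation. The p-values therefore measure the spread between these hybridisations, taken as the misfit of their ratios in the joint model. Part of it may be technical, and it can hold dye effects of single genes, since the model had no dye term. For each gene the same spread was assumed on all arrays.

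Spot intensity values, as the median pixel brightness of each spot and of its local background in each channel, were deposited as scanner output of Feature Extraction 10.7.3.1, per the file headers. The processed intensity of each channel, already background-subtracted, detrended over the slide and dye-normalised, and a log10 ratio of Cy5 over Cy3 were also made by Feature Extraction, per the file headers. A table of log2 ratios for the whole series was deposited by the authors, and limma is named without a version per the submitters' processing notes. That table held 14988 spots with 1 missing value, and 11 scanner spots were absent from it. Its scale and direction were read from the values: each column had a mean of 0, correlated across genes with the log2 ratios computed here at r from 0.950 to 0.993, and had a slope on them from 0.663 to 0.781. A positive value meant a higher Cy5 signal. The medians of its 6 columns were 0.0614, -0.0512, -0.0176, -0.0171, 0.0180 and -0.0950. It was taken as log2, since its log base and its normalisation are not given in the sources used here. All 6 arrays lay on 1 slide and were scanned together, so that neither slide nor scan could be examined as a batch.

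Each array had 14999 spots, of which 14312 held gene probes, 550 were positive controls and 137 were negative controls. The 12476 gene probes targeted 4102 genes. Most probes (12272) were spotted once, while 36 probes with names beginning QSense and 168 with names beginning PhotoGC were each spotted 10 times. The median number of probes per gene was 3. Median signals were corrected with normexp at an offset of 50 in limma 3.58.1 under R 4.3.3, normalised by loess within each array with control spots at weight 0, and averaged over the spots of a probe after spots marked as outliers were left out. The plan had named mean signals, and the files used here hold medians. A probe was kept where it was well above background in at least 2 of the 12 channels, which left 9925 probes and 3647 genes. A gene's value was the mean of its probes. One gene lacked a value on an array, so that 3646 genes were tested. The median signal per array lay between 1322 and 2167 in Cy3 and between 3218 and 4608 in Cy5. Negative control spots lay between 543 and 939 in Cy3 and between 947 and 1479 in Cy5, and from 66.3% to 78.1% of probes were well above background. No spot was saturated. The number of arrays limits the precision.

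The arrays were fitted together in limma with 5 conditions, delta-luxI1 as the reference and no dye term, which left 2 residual degrees of freedom (4.73 after moderation, from 2.73 prior degrees of freedom). All 10 pairwise comparisons of the conditions were taken from this model, 6 of which had an array of their own. P-values were adjusted by the Benjamini-Hochberg method within each comparison. Genes with an adjusted p under 0.05 were called, and a second count asked for an absolute log2 fold change of at least 1. Errors after ± are standard errors of the model unless stated as SD, and intervals are 95% intervals. The same fit was tested on simulated data for the 3646 genes, with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. At a log2 of 1 it recovered 90% for wild-type, 90% for C18-HSL, 87% for C18en-HSL and 93% for C18dien-HSL, each against delta-luxI1. At a log2 of 2 it recovered 100%, 100%, 97% and 97%. The false share of the calls was 5.47%, 9.09%, 4.66% and 4.52%. The simulated noise was independent between genes, had the same spread on all arrays and held no dye effects. Each figure came from a single draw in which only that condition changed. These rates therefore need not hold for the real calls.

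Where no probe of a gene was well above background in one condition, the change is given as at least N-fold. The bright condition's mean was set against the dim condition's mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own. These means used single channels after loess and Aquantile, and they are open to dye bias. The rule for named genes took the 10 highest and 10 lowest fold changes among called genes in each comparison with delta-luxI1, and 3 of each in the other comparisons. A gene also had to have the same direction on the direct array and in the fit without it, or in every fit without 1 array where no direct array existed. The rule, the model, the gene lists and the alternatives were chosen before the data were examined. The array's gene IDs are not paired with gene names in the files, and none matched the RefSeq gene table of assembly ASM1814v1. For this reason at most 2 IDs that rose and 2 that fell are given per comparison, next to members of the QSense and PhotoGC groups. The genes that the rule named by function (luxI1, luxR1, other AHL synthases and the CtrA pathway) could not be looked up. The deleted gene could therefore not be found by its ID to check the labels. The gene lists by function were likewise not tested. The QSense and PhotoGC groups come from the probe names of the array design and were defined only once the files had been opened. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and the p-values of both lists were adjusted together within each comparison. What the probe names stand for is not stated in the sources used here.

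Alternatives were a dye term in the model, Agilent processed signals, median centring in place of loess, no background subtraction, other filters on dim probes, the median of a gene's probes, the series table, separate-channel analysis (lmscFit), and leaving out each array in turn. In the separate-channel analysis the intraspot correlation was 0.359, and the estimate did not converge for 91 genes. Overlaps between comparisons that share the delta-luxI1 or the wild-type hybridisations were set against 100 simulated draws of unchanged conditions on the same arrays. The orientation of the arrays was examined with the sums around rings and with the SD of single-channel levels within conditions, after loess and Aquantile. Runs of neighbouring genes were examined in the order of the array's IDs, against 1000 permutations of that order.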

Results

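Transcript levels of Dinoroseobacter shibae were compared between wild-type cells, the delta-luxI1 mutant, and the mutant grown with C18-HSL, C18en-HSL or C18dien-HSL. The 3 AHLs share a long acyl chain and differ in its double bonds, of which C18-HSL has none, C18en-HSL has 1 and C18dien-HSL has 2. Each AHL was given at 500 nM, so that doses and sampling points matched. RNA was hybridised 2 times for wild-type, 3 times for delta-luxI1, 2 times for C18-HSL, 2 times for C18en-HSL and 3 times for C18dien-HSL. Across the 6 arrays, from 66.3% to 78.1% of probes were well above background, and 3646 genes were tested. The plot of called genes per comparison shows how many genes passed in each of the 10 pairwise comparisons.

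**Figure D1:**
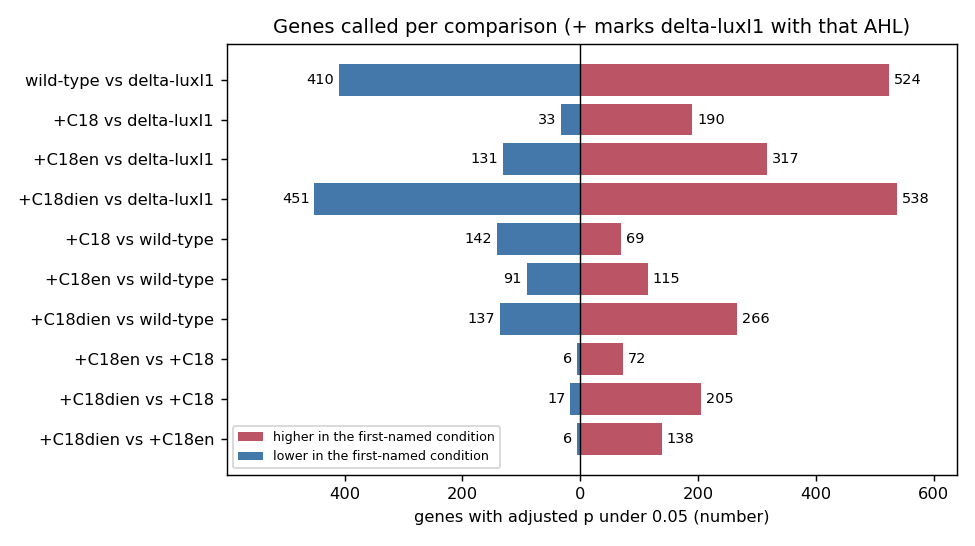
Number of genes with an adjusted p under 0.05 in each pairwise comparison, with genes higher in the first-named condition to the right of 0 and lower ones to the left. The bars reach 538 higher and 451 lower for C18dien-HSL against delta-luxI1, and 72 higher and 6 lower for C18en-HSL against C18-HSL.

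Each array's log ratios can be checked against the others, because the ratios around a closed ring of arrays should sum to 0 apart from noise and dye effects of single genes. Over the 4 arrays linking delta-luxI1, C18-HSL, C18en-HSL and C18dien-HSL, the sums had an SD of 0.291 across genes, the lowest of the 8 ways of turning the arrays (next 0.472). Over the 3 arrays linking wild-type, delta-luxI1 and C18dien-HSL, a ring examined only after the others, the SD was 0.415, the lowest of 4 (next 0.725). Around all 5 conditions the SD was 0.644, which ranked 3 of 16, and another way of turning the arrays gave 0.607. As labelled, the dye effects of all arrays add up in this ring, while they partly cancel in the ring of 4 arrays. The rank in the ring of 5 therefore does not decide the orientation. Turning every array at once leaves the SDs of these sums unchanged but changes which single-channel levels belong to a condition, a check added after the rings were seen. Over the 3646 genes, the SD between hybridisations of one condition was 0.161 as labelled, the lowest of the 64 ways of turning the 6 arrays (next 0.180), and 0.425 with every array turned. The direct ratios of wild-type over delta-luxI1 correlated across genes with those of C18dien-HSL over delta-luxI1 at a Pearson r of 0.808 and a Spearman rho of 0.488, and with those of C18-HSL over delta-luxI1 at 0.667 and 0.364. The C18-HSL over delta-luxI1 and C18dien-HSL over delta-luxI1 ratios correlated at 0.903 and 0.798. Those arrays both had delta-luxI1 in Cy3, so that dye effects of single genes enter both ratios alike and may raise the correlation. The wild-type array had delta-luxI1 in Cy5. Genes are not independent replicates, and each of these pairs of arrays has the delta-luxI1 condition in common. A dye coefficient added to the model was called in 837 genes (limma, adjusted p under 0.05), with a median size of 0.0521 over all genes on the log2 scale, and the model used for the comparisons had no such term. Cy5 was below Cy3 on all 6 arrays by over 0.5 log2 units in 10 genes and by over 1 in 3, and no gene did the opposite by over 0.5.

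The comparison of wild-type with delta-luxI1 asked which transcripts depend on luxI1. Transcripts of 524 genes were higher and of 410 genes lower in wild-type (limma, adjusted p under 0.05), and of these 195 were at least 2-fold higher and 44 at least 2-fold lower. RDRS02625 was at least 13.2-fold higher in wild-type, with a fitted log2 fold change of 4.80 ± 0.08 (limma, adjusted p = 6.88e-05), and was not well above background in delta-luxI1. RDRS03373 was higher by 4.72 ± 0.12 on the log2 scale (limma, adjusted p = 7.54e-05), which is 26.3-fold. Fold sizes depended on the processing, and RDRS02625 ranged from 3.38 in the series table to 6.33 with Agilent processed signals, and RDRS03373 from 3.48 to 5.86 between the same settings, with both calls kept. Among the genes that fell, RDRS03868 changed by -5.77 ± 0.15 (limma, adjusted p = 7.54e-05) and RDRS01201 by -2.30 ± 0.08 (limma, adjusted p = 0.000134). RDRS03868 differed between the strains and hardly with AHL. Its single-channel log2 level was 11.83 in wild-type and 17.02 in delta-luxI1. With C18-HSL, C18en-HSL and C18dien-HSL it was 16.96, 16.78 and 16.97. Each of these 4 genes had the same direction on the direct array and in the fit without it. The 10 highest changes ranged from 3.83 to 4.80 and the 10 lowest from -5.77 to -1.50. The number of called genes, 934, became 262 without the delta-luxI1 and C18dien-HSL array and 508 without the delta-luxI1 and C18-HSL, the C18-HSL and C18en-HSL or the C18en-HSL and C18dien-HSL array. Those last omissions all leave the ring of wild-type, delta-luxI1 and C18dien-HSL. They give the same fit of this comparison and are no separate checks. Agilent processed signals gave 488 higher and 631 lower and the series table split into 413 higher and 815 lower, so that the share of higher genes depended on the scaling.

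With C18-HSL, 190 genes were higher and 33 lower than in untreated delta-luxI1 (limma, adjusted p under 0.05), including 130 at least 2-fold higher and 17 at least 2-fold lower. RDRS02846, one of the QSense genes, was 21.8-fold higher (log2 4.45 ± 0.20; limma, adjusted p = 0.000591), and RDRS00048 was 14.9-fold higher (log2 3.90 ± 0.09; limma, adjusted p = 0.000347). Their log2 sizes ran from 3.46 to 5.30 and from 2.65 to 4.67 under other processing, lowest without background subtraction and highest with Agilent processed signals, and both stayed called. RDRS01295 fell by 1.39 ± 0.10 on the log2 scale (limma, adjusted p = 0.00277) and RDRS00812 by 1.32 ± 0.16 (limma, adjusted p = 0.0129). The 10 highest changes ranged from 3.14 to 4.45 and the 10 lowest from -1.39 to -1.07. Without the delta-luxI1 and C18-HSL array the count of 223 fell to 58, and neither RDRS01295 (-1.54) nor RDRS00812 (-1.62) was called. The count was 132 without the C18-HSL and C18en-HSL array or the C18en-HSL and C18dien-HSL array, where RDRS00812 (-1.21) was not called either, and 128 without the delta-luxI1 and C18dien-HSL array. The split of higher and lower genes was 497 and 330 with a dye term, 311 and 155 with separate channels, and 144 and 55 in the series table.

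With C18en-HSL, 317 genes were higher and 131 lower than in untreated delta-luxI1 (limma, adjusted p under 0.05), including 201 at least 2-fold higher and 34 at least 2-fold lower. RDRS00048 was 27.8-fold higher (log2 4.80 ± 0.10; limma, adjusted p = 0.000183), and RDRS03966 was 22.8-fold higher (log2 4.51 ± 0.11; limma, adjusted p = 0.000183). Their log2 sizes were 3.51 and 3.61 in the series table and 5.71 and 5.11 with Agilent processed signals, and both stayed called. RDRS00812 changed by -2.25 ± 0.18 (limma, adjusted p = 0.00205) and RDRS00659 by -2.14 ± 0.12 (limma, adjusted p = 0.000686). The 10 highest changes ranged from 4.06 to 4.80 and the 10 lowest from -2.25 to -1.81. No array held both conditions, so that the estimate ran through the others, and all 448 called genes kept their direction in every fit without 1 array. The count became 178 without the C18en-HSL and C18dien-HSL array, 182 without the delta-luxI1 and C18dien-HSL array, and 217 without the delta-luxI1 and C18-HSL or the C18-HSL and C18en-HSL array. Lower genes outnumbered higher ones under 3 other settings, at 710 higher and 789 lower with a dye term, 518 and 739 with separate channels, and 288 and 467 in the series table.

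With C18dien-HSL, 538 genes were higher and 451 lower than in untreated delta-luxI1 (limma, adjusted p under 0.05), including 246 at least 2-fold higher and 19 at least 2-fold lower. RDRS03373 was 30.9-fold higher (log2 4.95 ± 0.11; limma, adjusted p = 2.66e-05), and RDRS01127 was 26.2-fold higher (log2 4.71 ± 0.24; limma, adjusted p = 0.000251). The size of RDRS03373 was not exact, since it ran from 3.53 in the series table to 6.35 with Agilent processed signals, with the call kept. RDRS02459 changed by -2.003 ± 0.10 (limma, adjusted p = 0.000266) and RDRS02461 by -1.89 ± 0.08 (limma, adjusted p = 0.00013). The 10 highest changes ranged from 4.44 to 4.95 and the 10 lowest from -2.003 to -1.38. The count of 989 became 226 without the delta-luxI1 and C18dien-HSL array, and 473 without the delta-luxI1 and C18-HSL, the C18-HSL and C18en-HSL or the C18en-HSL and C18dien-HSL array. Those last omissions again give the same fit of the comparison and are no separate checks. The split of higher and lower genes was 523 and 858 with Agilent processed signals, 423 and 185 with median centring, 441 and 1477 in the series table, 820 and 1201 with a dye term, and 623 and 1096 with separate channels.

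The 12 genes with QSense probes included 2 that were higher in wild-type and with every AHL than in untreated delta-luxI1. RDRS02846 was higher by 4.46 ± 0.19 in wild-type, 4.45 ± 0.20 with C18-HSL, 4.42 ± 0.22 with C18en-HSL and 4.58 ± 0.17 with C18dien-HSL on the log2 scale (limma, adjusted p from 9.55e-05 to 0.000591). The AHLs did not differ detectably on RDRS02846, with a 95% interval of -0.55 to 0.50 for C18en-HSL minus C18-HSL, -0.37 to 0.68 for C18dien-HSL minus C18en-HSL and -0.46 to 0.72 for C18dien-HSL minus C18-HSL. RDRS02845 was not well above background in delta-luxI1 and was at least 2.22-fold higher in wild-type, 2.23-fold with C18-HSL, 2.92-fold with C18en-HSL and 2.89-fold with C18dien-HSL (limma, adjusted p from 6.86e-05 to 0.000583). Under other processing RDRS02846 ran from 3.43 to 5.44 over the 4 conditions and the fitted change of RDRS02845 from 0.99 to 3.76, with all calls kept, so that neither size was exact. RDRS00311 was higher in wild-type than in delta-luxI1 by 2.01 ± 0.08 (limma, adjusted p = 0.000155), while its changes with the AHLs were 0.11, 0.09 and 0.02 (limma, adjusted p = 0.681, 0.616 and 0.85). Its probes disagreed: 4 probes, not well above background in any channel of the delta-luxI1 strain, were at least 3.17- to 3.64-fold higher in wild-type, and 2 were lower, at -0.86 and -0.95 on the log2 scale. The mean of 2.01 included the 4 dim probes and was no exact size. Where only probes well above background in all 12 channels were used, those last 2 remained and RDRS00311 turned to -0.90 in wild-type. The plot of the QSense genes shows each change with its interval.

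**Figure D2:**
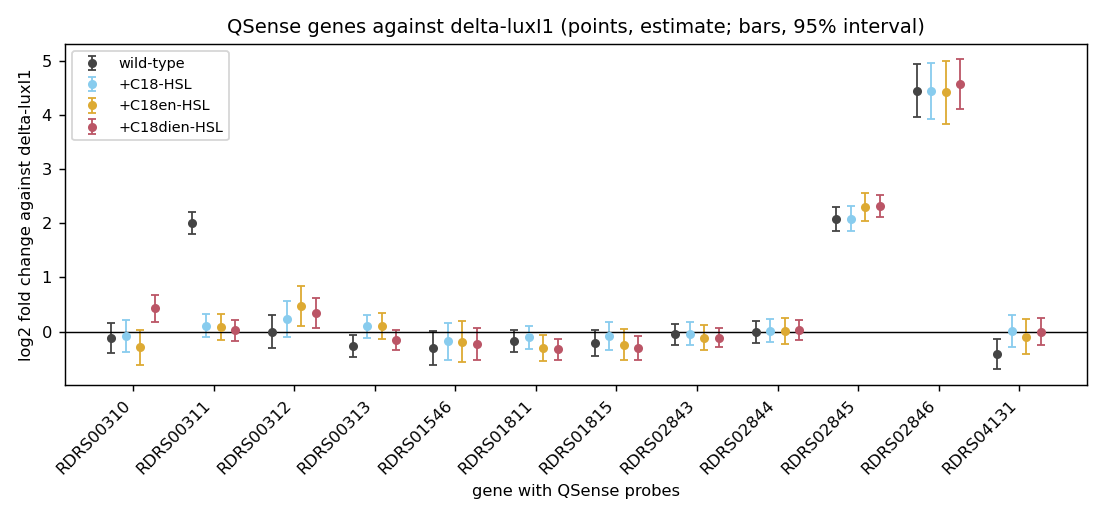
Log2 fold change against untreated delta-luxI1 of the 12 genes with QSense probes, for wild-type and the 3 AHLs, with 95% intervals. RDRS02846 lies between 4.42 and 4.58 in all 4 conditions, and RDRS00311 lies at 2.01 in wild-type and at 0.02 to 0.11 with the AHLs, from probes that disagree in direction.

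As a group, the QSense genes held 3 higher and 1 lower member in wild-type (3 and 2 when adjusted over the list alone), 2 higher members with C18-HSL (2 over the list alone), 2 with C18en-HSL (2 over the list alone), and 3 higher and 1 lower with C18dien-HSL (3 and 2 over the list alone). The lower member in wild-type was RDRS04131 at -0.42 (limma, adjusted p = 0.047), and those called with C18dien-HSL beside RDRS02846 and RDRS02845 were RDRS00310 at 0.43 (limma, adjusted p = 0.0352) and RDRS01811 at -0.33 (limma, adjusted p = 0.0319). Over the fits without 1 array, RDRS04131 kept its call only without the C18dien-HSL and wild-type array, and it changed by -0.20 without the wild-type and delta-luxI1 array. It also lost its call in 4 of 9 other settings, which put it between -0.67 and -0.27, while RDRS00310 lost its call with median centring and with the median of probes, and RDRS01811 with median centring. RDRS00310 and RDRS01811 were not called without the delta-luxI1 and C18-HSL, the C18-HSL and C18en-HSL, the C18en-HSL and C18dien-HSL or the delta-luxI1 and C18dien-HSL array, where RDRS00310 lay between 0.30 and 0.42 and RDRS01811 between -0.36 and -0.30. Set against all other genes with camera, the QSense group did not pass (adjusted p = 0.874, 0.119, 0.371 and 0.325 for wild-type, C18-HSL, C18en-HSL and C18dien-HSL). Fry, which asks whether the members move one way on balance, gave adjusted p = 0.00705, 0.023, 0.0262 and 0.0151. The group's median and mean differed in sign for wild-type (-0.08 and 0.58) and C18en-HSL (-0.04 and 0.51).

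All 57 genes with PhotoGC probes were measured, and their median log2 change against delta-luxI1 was 0.16 in wild-type, 0.25 with C18-HSL, 0.41 with C18en-HSL and 0.53 with C18dien-HSL. Of these genes 14 were higher and 2 lower in wild-type (15 and 2 when adjusted over the list alone), 1 was higher with C18-HSL (1 over the list alone), 8 were higher with C18en-HSL (19 over the list alone) and 41 were higher with C18dien-HSL (45 higher and 3 lower over the list alone). RDRS03493 was higher in all 4, by at least 4.95-fold in wild-type, 1.69-fold with C18-HSL, 2.78-fold with C18en-HSL and 4.08-fold with C18dien-HSL (limma, adjusted p from 3.66e-05 to 0.00104). With camera at the preset correlation the PhotoGC group was higher in wild-type (adjusted p = 0.00159), with C18-HSL (adjusted p = 1.03e-08), with C18en-HSL (adjusted p = 8.32e-11) and with C18dien-HSL (adjusted p = 4.78e-12). With an estimated correlation none of these calls held (adjusted p = 0.883, 0.306, 0.445 and 0.409), and with fry the adjusted p was 0.107, 0.123, 0.0625 and 0.0263. Without the C18dien-HSL and wild-type array the wild-type shift no longer passed camera (adjusted p = 0.117), and without the delta-luxI1 and C18-HSL array the C18-HSL shift turned downward (adjusted p = 0.56).

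The number of called PhotoGC genes changed with the arrays fitted. Each fit without 1 array has 1 residual degree of freedom in place of 2, so that a lost call need not be a lost change. The log2 change of RDRS03493 with C18dien-HSL, for instance, stayed between 2.66 and 2.74 over these fits. The 41 genes with C18dien-HSL became 1 without the delta-luxI1 and C18dien-HSL array and 13 without the delta-luxI1 and C18-HSL, the C18-HSL and C18en-HSL or the C18en-HSL and C18dien-HSL array. For wild-type the same omissions turned 14 higher PhotoGC genes into 1 and 8. For C18en-HSL each of these omissions turned 8 into 1, while leaving out either wild-type array gave 26. With C18-HSL, RDRS03493 was the 1 called PhotoGC gene and was not called without the delta-luxI1 and C18-HSL array, while 4 PhotoGC genes were called without either wild-type array. Between AHLs, the median PhotoGC difference was 0.14 for C18en-HSL minus C18-HSL, 0.24 for C18dien-HSL minus C18-HSL and 0.09 for C18dien-HSL minus C18en-HSL, with camera adjusted p = 2.84e-07, 8.79e-08 and 0.00973. These too were lost with an estimated correlation (adjusted p = 0.669, 0.66 and 0.89). Compared with wild-type, 8 PhotoGC genes were higher with C18dien-HSL (15 higher and 1 lower over the list alone) at a median of 0.21, with camera adjusted p = 5.68e-06, or adjusted p = 0.435 with an estimated correlation. C18-HSL and C18en-HSL each had 0 higher and 1 lower PhotoGC gene against wild-type, at medians of 0.02 and 0.14. Camera gave adjusted p = 0.906 and 0.00182 for them, or 0.981 and 0.6 with an estimated correlation.

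Against wild-type, the mutant with C18-HSL had 69 genes higher and 142 lower (limma, adjusted p under 0.05), of which 27 were at least 2-fold higher and 104 at least 2-fold lower. RDRS03868 was higher by 5.82 ± 0.20 on the log2 scale (limma, adjusted p = 0.00318), and RDRS02274 was at least 5.71-fold higher (limma, adjusted p = 0.00318). RDRS03868 was about as high in untreated delta-luxI1 (single-channel log2 level 17.02) as with C18-HSL (16.96). RDRS01580 was at least 9.97-fold lower and RDRS01618 at least 5.33-fold lower (limma, adjusted p = 0.00355 for each). In other settings the fitted change ran from 1.77 to 4.46 for RDRS02274, from -4.89 to -2.44 for RDRS01580 and from -4.18 to -1.75 for RDRS01618, so that these bounds depend on the processing. Without the delta-luxI1 and C18-HSL array no gene was called (limma; 347 at an unadjusted p under 0.05), and these 4 kept their direction without passing. The count was 54 without the C18-HSL and C18en-HSL or the C18en-HSL and C18dien-HSL array and 59 without the delta-luxI1 and C18dien-HSL array. The split was 29 higher and 111 lower with median centring, but close to even with a dye term (639 and 652), separate channels (439 and 464) and probes above background in all 12 channels (14 and 13).

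With C18en-HSL, 115 genes were higher and 91 lower than in wild-type (limma, adjusted p under 0.05), of which 65 and 43 differed at least 2-fold. RDRS03868 was higher by 5.47 ± 0.20 and RDRS00048 by 2.52 ± 0.11 on the log2 scale (limma, adjusted p = 0.00781 for each). The single-channel log2 level of RDRS03868 was 16.78 with C18en-HSL and 17.02 in untreated delta-luxI1. RDRS01580 was lower, at -3.13 ± 0.17 (limma, adjusted p = 0.0102), as was RDRS01618, at -2.15 ± 0.15 (limma, adjusted p = 0.0107). In other settings RDRS03868 ran from 4.80 to 5.64, RDRS01580 from -4.19 to -2.27 and RDRS01618 from -3.10 to -1.53, with the calls kept. Only 2 genes, RDRS03868 and RDRS01580, were called without the delta-luxI1 and C18-HSL or the C18-HSL and C18en-HSL array. None was called without the C18en-HSL and C18dien-HSL array or the delta-luxI1 and C18dien-HSL array (limma; 346 and 500 at an unadjusted p under 0.05), whereas separate-channel analysis of all arrays called 364 higher and 509 lower and a dye term 554 higher and 706 lower. Probes above background in all 12 channels gave 54 higher and 16 lower.

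With C18dien-HSL, 266 genes were higher and 137 lower than in wild-type (limma, adjusted p under 0.05), of which 66 were at least 2-fold higher and 8 at least 2-fold lower. RDRS03868 was higher by 5.35 ± 0.15 on the log2 scale (limma, adjusted p = 0.0011), and RDRS02274 was at least 8.64-fold higher (limma, adjusted p = 0.000574). The single-channel log2 level of RDRS03868 was 16.97 with C18dien-HSL and 17.02 in untreated delta-luxI1. RDRS00311 was lower, at -1.99 ± 0.08 (limma, adjusted p = 0.00222) from probes that disagree in direction, as was RDRS01238, at -1.34 ± 0.27 (limma, adjusted p = 0.0455). RDRS01238 ranged from -2.03 to -0.95 over the fits without 1 array and was called only without one or the other wild-type array. It ranged from -1.50 to -0.40 over other settings and lost its call in 3 of 9. RDRS02274 ran from 2.39 to 4.97, and RDRS00311 turned to 1.09 with probes above background in all 12 channels. No gene was called without the delta-luxI1 and C18dien-HSL array (limma; 581 at an unadjusted p under 0.05), 174 were called without the C18dien-HSL and wild-type array, and 103 without the delta-luxI1 and C18-HSL, the C18-HSL and C18en-HSL or the C18en-HSL and C18dien-HSL array. Those last omissions give the same fit of this comparison too. The split of higher and lower genes was 144 and 29 with median centring, 270 and 320 in the series table, 764 and 913 with a dye term, and 502 and 548 with separate channels.

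The genes at least 2-fold higher in wild-type than in delta-luxI1, 195 in number, were followed through the AHLs, a set chosen after the counts were seen. Their median log2 change against delta-luxI1 was 2.15 in wild-type, 1.06 with C18-HSL, 1.73 with C18en-HSL and 2.69 with C18dien-HSL, and 123, 167 and 189 of them were called higher with C18-HSL, C18en-HSL and C18dien-HSL. In 173 of the 195 the estimates were ordered C18-HSL, C18en-HSL, C18dien-HSL from low to high, where equal odds for each order would give 32.5. That figure is no test, since neighbouring genes change together and every order comes from the same hybridisations. The wild-type estimate that chose the set also runs partly through the C18dien-HSL arrays. Compared directly, 69 were higher with C18en-HSL than with C18-HSL, 92 with C18dien-HSL than with C18en-HSL and 159 with C18dien-HSL than with C18-HSL (limma, adjusted p under 0.05). These differences were positive in 189, 178 and 192 of the 195 genes. Without any 1 of the 4 arrays that hold no wild-type RNA, limma called 0 of the 195 for the first 2 differences (102 to 147 and at most 115 at an unadjusted p under 0.05) and 44 to 75 for the third. The differences then stayed positive in 186 to 189, 174 to 175 and 191 to 193 genes. With Agilent processed signals, limma called 0, 43 and 124 of the 195 (163, 116 and 176 at an unadjusted p under 0.05), and with a dye term 176, 129 and 185. Against wild-type itself, 118 of these genes were lower and 9 higher with C18-HSL, 72 lower and 33 higher with C18en-HSL, and 21 lower and 57 higher with C18dien-HSL. These became, without the delta-luxI1 and C18dien-HSL array, 51 lower and 1 higher with C18-HSL, and limma called 0 with C18en-HSL and C18dien-HSL (164 and 97 at an unadjusted p under 0.05). Limma called 0 with C18-HSL without the delta-luxI1 and C18-HSL array (154 at an unadjusted p under 0.05). Chosen on the wild-type and delta-luxI1 array alone, 205 genes had median log2 ratios of 0.96 for C18-HSL over delta-luxI1, 0.62 for C18en-HSL over C18-HSL and 0.65 for C18dien-HSL over C18en-HSL on the other arrays. The plot of this set shows its spread in each condition.

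**Figure D3:**
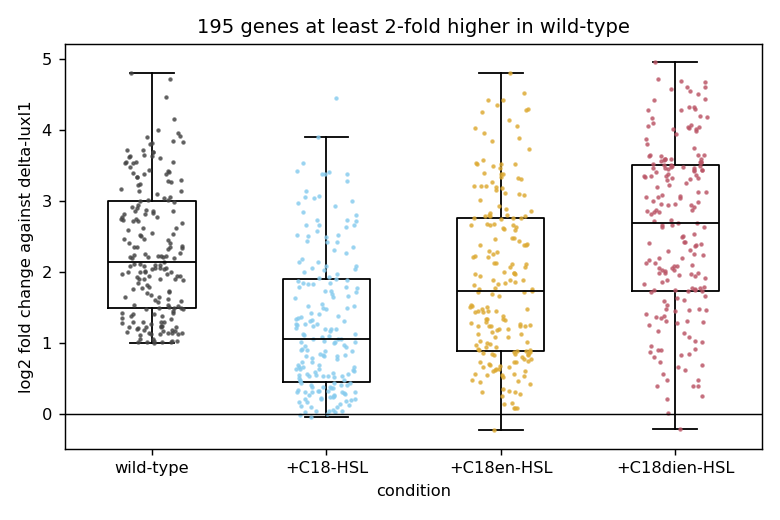
Log2 fold change against untreated delta-luxI1 of the 195 genes at least 2-fold higher in wild-type, for wild-type and the 3 AHLs, with a point per gene, boxes for the median and quartiles, and whiskers for the range apart from distant genes. The medians are 2.15, 1.06, 1.73 and 2.69, and the genes were chosen on the wild-type values shown first.

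The 44 genes at least 2-fold lower in wild-type had median log2 changes of -1.37 in wild-type, -0.51 with C18-HSL, -1.06 with C18en-HSL and -0.83 with C18dien-HSL, and 18, 35 and 41 of them were called lower with the AHLs in that order. In 26 of the 44 the fall grew from C18-HSL to C18en-HSL to C18dien-HSL, and in 15 it was largest with C18en-HSL and smallest with C18dien-HSL, against 7.33 for each order at equal odds. These genes are not independent either, so that 7.33 is no test. Directly compared, 13 of the 44 were higher and 4 lower with C18dien-HSL than with C18en-HSL (limma), and 0 passed without any 1 of the 4 arrays that hold no wild-type RNA (limma; 23 to 25 at an unadjusted p under 0.05). Without the delta-luxI1 and C18dien-HSL array, 12, 18 and 10 of the 44 were called lower with the AHLs in the order above.

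C18en-HSL and C18-HSL, which differ by 1 double bond, differed in 78 genes, 72 higher and 6 lower with C18en-HSL (limma, adjusted p under 0.05). RDRS01080 was higher by 1.27 ± 0.14 and RDRS03354 by 1.07 ± 0.09 on the log2 scale (limma, adjusted p = 0.0372 for each). RDRS00659 was lower, at -0.998 ± 0.11 (limma, adjusted p = 0.0372), and RDRS01656 at -0.92 ± 0.13 (limma, adjusted p = 0.0478). These genes are 4 of the 78, and none of them passed without the delta-luxI1 and C18-HSL, the C18-HSL and C18en-HSL, the C18en-HSL and C18dien-HSL or the delta-luxI1 and C18dien-HSL array, where limma called 0 genes (317, 184, 317 and 299 at an unadjusted p under 0.05). Without either wild-type array 151 genes were called. Limma also called 0 genes with Agilent processed signals, median centring, the series table or probes above background in all 12 channels (513, 341, 555 and 270 at an unadjusted p under 0.05), whereas a dye term gave 410 higher and 261 lower and separate channels 231 higher and 69 lower. RDRS01080 was not called with the median of probes either.

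C18dien-HSL and C18-HSL differed in 222 genes, 205 higher and 17 lower with C18dien-HSL (limma, adjusted p under 0.05), of which 129 were at least 2-fold higher and 6 at least 2-fold lower. RDRS03354 was higher by 2.88 ± 0.10 on the log2 scale (limma, adjusted p = 0.00166), and RDRS01580 was at least 5.87-fold higher (limma, adjusted p = 0.00202). RDRS02769 was lower, at -1.47 ± 0.10 (limma, adjusted p = 0.00302), and RDRS01201 at -1.26 ± 0.10 (limma, adjusted p = 0.00428). Neither of these last genes passed without the delta-luxI1 and C18-HSL array (-1.58 and -1.17) or the delta-luxI1 and C18dien-HSL array (-1.47 and -1.26), where 44 and 63 genes were called. In other settings RDRS03354 ran from 2.41 to 3.53 and RDRS01580 from 1.77 to above 4, with the calls kept, and RDRS01201 lost its call with median centring. The count was 77 without the C18-HSL and C18en-HSL or the C18en-HSL and C18dien-HSL array, and the series table split into 188 higher and 46 lower. The excess of higher genes was much smaller with a dye term, at 560 higher and 471 lower, and with separate channels, at 385 and 267.

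C18dien-HSL and C18en-HSL, again 1 double bond apart, differed in 144 genes, 138 higher and 6 lower with C18dien-HSL (limma, adjusted p under 0.05), of which 71 were at least 2-fold higher and 1 at least 2-fold lower. RDRS01466 was higher by 2.41 ± 0.14 and RDRS01580 by 2.38 ± 0.13 on the log2 scale (limma, adjusted p = 0.00653 for each), and RDRS01580 ran from 1.60 to 3.50 in other settings with the call kept. RDRS02769 was lower, at -1.26 ± 0.09 (limma, adjusted p = 0.00845), and RDRS01467 at -0.95 ± 0.08 (limma, adjusted p = 0.0104). None of the 4 passed without the delta-luxI1 and C18-HSL, the C18-HSL and C18en-HSL, the C18en-HSL and C18dien-HSL or the delta-luxI1 and C18dien-HSL array, where limma called 0 genes (250, 250, 190 and 232 at an unadjusted p under 0.05). On all arrays, Agilent processed signals gave 66 higher and 4 lower, probes above background in all 12 channels 17 and 1, separate channels 213 and 26, and a dye term 313 and 150.

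The genes changed in wild-type overlapped with those changed by each AHL. Wild-type and C18-HSL shared 156 higher and 32 lower genes, wild-type and C18en-HSL 242 and 104, and wild-type and C18dien-HSL 363 and 248. Independent lists of those sizes would share 27.3 and 3.71, 45.6 and 14.7, and 77.3 and 50.7 genes, and unchanged conditions simulated on the same arrays shared at most 0, 0 and 1. The simulated data held no changed gene, so that few genes could be called and an overlap near 0 was fixed in advance. Their counts cannot show how much overlap shared hybridisations add to lists of the real size. Without the delta-luxI1 and C18dien-HSL array the shared genes became 91 and 13, 124 and 20, and 168 and 12, and without the delta-luxI1 and C18-HSL array 54 and 1, 151 and 25, and 258 and 73. Among genes called in both comparisons, only 2 with C18en-HSL and 3 with C18dien-HSL were called in the direction opposite to wild-type. Across genes, the fold changes of wild-type correlated with those of the 3 AHLs, in order of their double bonds, at r = 0.759, 0.813 and 0.882, against 0.14, 0.237 and 0.454 in the simulations. The covariances were 0.219, 0.335 and 0.439, against 0.00601, 0.0086 and 0.0131. All of these comparisons use the same delta-luxI1 hybridisations, and part of the excess in the joint model may come from them. Single arrays with separate delta-luxI1 hybridisations correlated at r = 0.667 for wild-type with C18-HSL and 0.808 for wild-type with C18dien-HSL, while C18en-HSL had no array with delta-luxI1.

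The AHLs overlapped with one another as well. C18-HSL and C18en-HSL shared 190 higher and 33 lower genes, C18-HSL and C18dien-HSL 190 and 27, and C18en-HSL and C18dien-HSL 317 and 114, where independent lists would share 16.5 and 1.19, 28 and 4.08, and 46.8 and 16.2. Simulated unchanged conditions shared at most 1, 0 and 1, which was again fixed near 0 because no simulated gene changed. The AHLs shared, without the delta-luxI1 and C18dien-HSL array, 114 and 13, 114 and 1, and 157 and 4 genes. In the fit without the delta-luxI1 and C18-HSL array, 57 genes were called higher and 1 lower with C18-HSL, the 57 were shared with each other AHL, and C18en-HSL and C18dien-HSL shared 190 and 20. Correlations were 0.966, 0.894 and 0.936, against 0.556, 0.277 and 0.505 simulated, and covariances 0.265, 0.295 and 0.442, against 0.0222, 0.00857 and 0.0171. Single arrays with separate delta-luxI1 hybridisations correlated at r = 0.903 for C18-HSL with C18dien-HSL. Both arrays had delta-luxI1 in Cy3 and the AHL in Cy5, so that shared dye effects may raise this value. For every pair, part of the excess in the joint model may come from the shared hybridisations, and the labels do not tie separate cultures to the delta-luxI1 hybridisations. In all, 156 genes were higher and 27 lower in wild-type and with each AHL, and fewer were without any 1 of the 4 arrays that hold no wild-type RNA. Another 375 genes called with C18dien-HSL were not called in wild-type. Over these 375, higher and lower together, the median log2 difference of C18dien-HSL minus wild-type was -0.04. How many of them were called in that comparison was not counted.

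Neighbouring gene IDs changed together, a pattern examined after the counts were seen. The longest run of consecutive IDs higher in wild-type than in delta-luxI1 held 22 genes and the longest lower run 11, while 1000 permutations of the ID order gave at most 8 and 6. In the 22-gene run the mean log2 change against delta-luxI1 was 3.09 ± 0.83 (SD over genes) in wild-type, 1.45 ± 0.51 with C18-HSL, 2.25 ± 0.66 with C18en-HSL and 3.11 ± 0.73 with C18dien-HSL. All 22 genes were higher with C18dien-HSL than with C18-HSL (limma, adjusted p under 0.05), of which 8 to 17 passed without any 1 of the 4 arrays that hold no wild-type RNA. Runs of 16 and 15 genes had another profile, with means of 2.17 and 2.14 in wild-type, 2.73 and 2.77 with C18-HSL, 3.59 and 3.58 with C18en-HSL and 3.76 and 3.68 with C18dien-HSL. Of the 16 genes, 16 were higher with C18dien-HSL than in wild-type and 15 with C18en-HSL, and of the 15 genes, 15 and 14. Limma called 0 of these genes with C18dien-HSL without the delta-luxI1 and C18dien-HSL array, and 0 with C18en-HSL without any 1 of the 4 arrays that hold no wild-type RNA, though all 16 and all 15 passed at an unadjusted p under 0.05. Between C18dien-HSL and C18en-HSL the mean difference was 0.16 ± 0.08 over the 16 genes and 0.10 ± 0.08 over the 15 genes (SD over genes). A lower run of 8 genes, which begins with RDRS00659, had means of -1.14 in wild-type, -0.86 with C18-HSL, -1.44 with C18en-HSL and -0.55 with C18dien-HSL, and 6 of its genes were higher with C18dien-HSL than with C18en-HSL, of which 0 passed without any 1 of those 4 arrays (limma; 7 of the 8 genes at an unadjusted p under 0.05). The other lower run of 8 genes, which ends with RDRS02461, had means of -1.36, -0.65, -1.09 and -1.39, and its mean difference between C18dien-HSL and C18en-HSL was -0.30 ± 0.12 (SD over genes). The plot of runs gives all 9 runs of at least 8 genes.

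**Figure D4:**
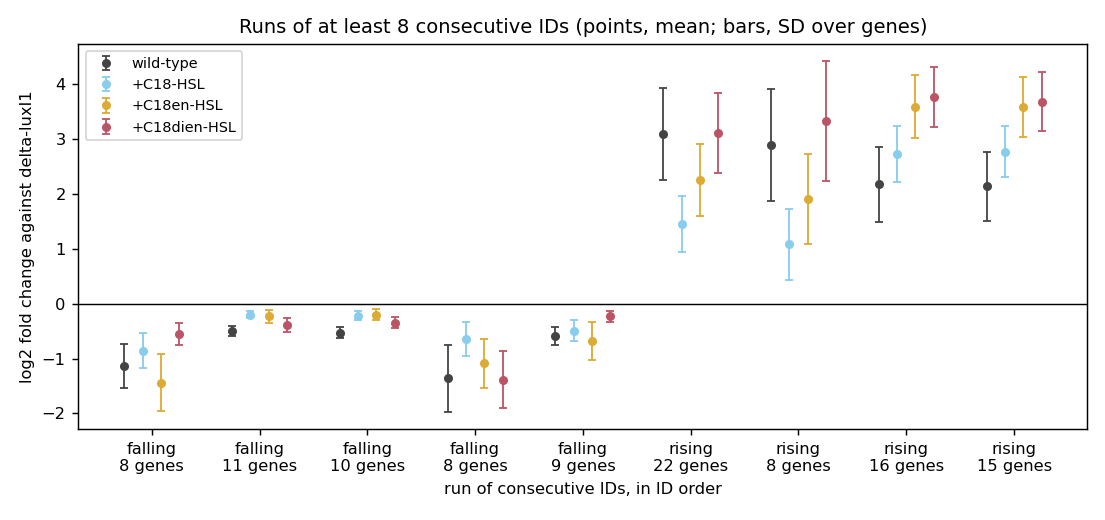
Mean log2 fold change against untreated delta-luxI1 over the genes of each run of at least 8 consecutive IDs called in one direction in wild-type, for wild-type and the 3 AHLs, with SD over the genes. The 22-gene run reaches 3.09 in wild-type and 3.11 with C18dien-HSL, while the runs of 16 and 15 genes reach 2.17 and 2.14 in wild-type and 3.76 and 3.68 with C18dien-HSL.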

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

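The tests of array orientation were chosen only after the result was seen. The differences between AHLs stood out because the response to one AHL was tested directly against the response to another: limma called 78 genes between C18en-HSL and C18-HSL, 222 between C18dien-HSL and C18-HSL, and 144 between C18dien-HSL and C18en-HSL. Over the fits without 1 array the count of 78 ran from 0 to 151, the count of 222 from 44 to 280 and the count of 144 from 0 to 189, and the low values came without any 1 of the 4 arrays that hold no wild-type RNA (184 to 317 and 190 to 250 genes at an unadjusted p under 0.05 beside the counts of 0). In each of those fits the spread came from a ring of arrays that includes wild-type, and such rings closed less well than the ring of 4 arrays. The low values therefore do not single out any array. Probe ETG10_195139, listed among the control spots and used in no comparison, was well above background in 10.8 of the 12 channels on average, with median signals of 1452 in Cy3 and 2568 in Cy5, while the next control probe reached 0.167 channels.

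The genes at least 2-fold higher in wild-type were ordered C18-HSL, C18en-HSL, C18dien-HSL in 173 of 195 cases. A dye effect would need a dye estimate about as large as the steps between AHLs, and the median estimate from the 4 arrays in which the conditions cancel was -0.057 (quartiles -0.145 and 0.0419), against median steps of 0.67 and 0.714. Normalisation as the whole cause was argued against by Agilent processed signals, with which 173 genes had this order, 170 of them the same genes. An array labelled in the wrong orientation was argued against by the ring of 4 arrays that link the AHLs, where the labelled orientation had the lowest SD by 0.181 (95% of resampled gene sets between 0.147 and 0.215), although the ring of 5 arrays ranked it 3 of 16. In that ring of 5 the dye effects of all arrays add up as labelled, so that its rank does not decide the orientation. All arrays turned together was argued against by single-channel levels, whose SD within conditions over all genes was 0.161 as labelled and larger by 0.264 with all arrays turned (95% of resampled gene sets between 0.244 and 0.286). What stays open is a biological difference between the AHLs, which may be a graded response to the number of double bonds as a hypothesis, and a difference between single cultures, since C18-HSL and C18en-HSL had 2 hybridisations each.

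For the 989 genes called between delta-luxI1 with and without C18dien-HSL, other splits of the same 6 hybridised channels into groups of 3 were counted. With 10 splits the share can never lie under 0.05. The real split was the 1 of 10 with as many genes, at 989, and the highest of the others called 0 genes in limma. Each other split mixes channels of both conditions, so that any difference between the conditions enters the spread. A count near 0 was therefore likely in advance there, and 989 against 0 decides nothing.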

How the results depend on the processing

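The alternatives for counts and named genes and the kinds of list test were planned, while the QSense and PhotoGC lists were defined only once the files had been opened, and the order of the genes higher in wild-type and the PhotoGC counts were followed only after the result was seen. Slide as a random block was not run, since all arrays lay on 1 slide. No named change that was called in the main fit or in the alternative reversed, except RDRS00311. Of the 158 named values 55 were called, and a change of sign was not counted where neither fit called the value. The uncalled change of RDRS00310 in wild-type against delta-luxI1, for instance, ran from -0.24 to 0.11 over the fits without 1 array. With the dye term 29 values newly passed, 25 with separate channels, 9 with the series table and 5 with processed signals. Lost were 10 with median centring, 7 with processed signals, 6 with probes above background in all 12 channels and 4 with the series table. Leaving out 1 array kept 855 calls or non-calls, lost 90 and added 3. Fold sizes of named genes also depended on the processing, most often smallest without background subtraction or in the series table and largest with processed signals. With probes above background in all 12 channels, RDRS00311 turned to -0.904 (wild-type against delta-luxI1) and 1.10, 1.12 and 1.09 (C18-HSL, C18en-HSL and C18dien-HSL against wild-type), because only its 2 opposed probes stay. The order count lay between 166 and 179 of 195 where all genes were present, and was 58 of 76 with probes above background in all 12 channels. Dim signal limits the bounded changes: 89 of the 934 genes called in wild-type against delta-luxI1 were below background in one of both.

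Counts that moved by over 1.5 times are given in the order wild-type, C18-HSL, C18en-HSL and C18dien-HSL against delta-luxI1, then C18-HSL, C18en-HSL and C18dien-HSL against wild-type, then C18en-HSL against C18-HSL, C18dien-HSL against C18-HSL and C18dien-HSL against C18en-HSL. A dye term gave 2032, 827, 1499, 2021, 1291, 1260, 1677, 671, 1031 and 463 genes, all with fewer residual degrees of freedom (1) but 16.9 prior degrees of freedom in place of 2.73. It held every gene called without it. Separate channels gave 1469, 466, 1257, 1719, 903, 873, 1050, 300, 652 and 239. Median centring gave 564 for wild-type and 608 for C18dien-HSL against delta-luxI1, 140, 121 and 173 against wild-type, and 0 for C18en-HSL against C18-HSL (limma, 341 at an unadjusted p under 0.05). Probes above background in all 12 channels, with fewer genes tested, gave 80 and 218 for C18-HSL and C18en-HSL against delta-luxI1, 27, 70 and 256 against wild-type, and 0 (270 unadjusted), 58 and 18 between AHLs. The series table gave 755 and 1918 for C18en-HSL and C18dien-HSL against delta-luxI1 and 0 for C18en-HSL against C18-HSL (555 unadjusted). Processed signals gave 0 (513 unadjusted) for that pair and 70 for C18dien-HSL against C18en-HSL. Except where a construction is named, the cause was not tested.

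Over the fits without 1 array the counts ran from 262 to 901, 58 to 293, 178 to 625, 226 to 1312, 0 to 242, 0 to 254, 0 to 399, 0 to 151, 44 to 280 and 0 to 189 in the same order. Each such fit has 1 residual degree of freedom in place of 2, and a condition left with 1 hybridisation is assumed to vary like the others. That degree of freedom comes from the ring of arrays left. Without an array that holds no wild-type RNA, this ring includes wild-type. The SD of the sums over the square root of the number of arrays was 0.24 and 0.288 in such rings. It was 0.145 in the ring of 4 arrays left without a wild-type array. Lost calls may reflect this spread rather than the array left out, and omissions that leave the same ring can give the same fit. The QSense list, which camera did not call, passed with fry (adjusted p = 0.00705, 0.023, 0.0262 and 0.0151 for wild-type, C18-HSL, C18en-HSL and C18dien-HSL). The PhotoGC list lost its call with an estimated correlation (adjusted p = 0.883, 0.306, 0.445 and 0.409) and, for the first 3, with fry (0.107, 0.123 and 0.0625). Without 1 array, its camera adjusted p ran from 8.59e-06 to 0.117 in wild-type and from 8.74e-14 to 0.56 with C18-HSL, the last downward. It ran from 2.33e-15 to 7.74e-05 with C18en-HSL and from 1.5e-12 to 6.35e-11 with C18dien-HSL. Without background subtraction, without a filter on dim probes and with the median of probes, all 10 counts stayed within 1.5 times.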

Other observations

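The tests of the RDRS00311 probes were chosen only after the result was seen. Transcripts of 45 genes were higher than in wild-type with each of the 3 AHLs, with median log2 differences of 0.97 for C18-HSL, 1.48 for C18en-HSL and 1.28 for C18dien-HSL, while their median in wild-type was 0.23 above delta-luxI1. Transcripts of 22 genes were lower than in wild-type with each AHL, and their median change against delta-luxI1 was 1.14 in wild-type and 0.08, 0.10 and 0.19 with C18-HSL, C18en-HSL and C18dien-HSL. All 3 comparisons use the same wild-type hybridisations, and part of the excess over independent lists, which would share 0.159 and 0.133 genes, may come from them. The 100 simulated draws of unchanged conditions gave at most 0 such genes in limma. With no changed gene in these draws, a count near 0 was fixed in advance, so that they do not measure that part. The 45 and 22 genes became 16 and 9 with median centring and 11 and 1 with probes above background in all 12 channels, but 51 and 37 in the series table and 358 and 325 with a dye term. They became 1 and 1 without the C18-HSL and C18en-HSL array. None was left without the delta-luxI1 and C18-HSL array, the C18en-HSL and C18dien-HSL array or the delta-luxI1 and C18dien-HSL array, since limma then called 0 genes against wild-type for C18-HSL (347 at an unadjusted p under 0.05), for C18en-HSL (346) and for C18en-HSL and C18dien-HSL (500 and 581), in that order.

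The 34 genes at least 2-fold lower with C18en-HSL than in delta-luxI1 had medians of -1.50 with C18en-HSL, -1.32 in wild-type and -0.71 with C18dien-HSL. Of these, 33 were also called lower in wild-type, 24 with C18-HSL and 29 with C18dien-HSL. Directly compared, 18 of the 34 were higher with C18dien-HSL than with C18en-HSL (limma), a set chosen on its C18en-HSL values, which favours such a return, and 0 passed without any 1 of the 4 arrays that hold no wild-type RNA (limma; 22 to 28 at an unadjusted p under 0.05).

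In RDRS00311, 4 probes were higher and 2 lower in wild-type than in delta-luxI1. A dye effect was argued against by the direction of the 4 probes, all higher in the wild-type channel on both wild-type arrays, where wild-type had opposite dyes: their Cy5 over Cy3 ratios averaged 0.115 on the log2 scale over both arrays. As bounds, these probes were at least 3.17- to 3.64-fold higher in wild-type. A candidate explanation is that part of this gene is missing from the delta-luxI1 strain: the 4 probes were well above background in 0 of 40 measurements of that strain with or without AHLs, and in 8 of 8 of wild-type. These measurements follow the strain that the labels give to each channel. They are not independent, since the probes share the same hybridisations. On the wild-type and delta-luxI1 array the 4 probes also formed close pairs, at log2 Cy5 over Cy3 of -3.89 and -4.16 and of -2.78 and -2.70. Whether paired probes cover the same position was not examined. The lack of signal well above background fits a deletion but does not exclude a transcript that is merely low there, and probe sequences were not used here. The gene deleted in this strain is luxI1, and whether RDRS00311 is luxI1 could not be looked up. Its other 2 probes were well above background in that strain. No biological explanation was tested.

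The runs of 16 and 15 neighbouring genes were higher with C18dien-HSL than in wild-type by 1.57 on average over their 31 genes. A dye effect was argued against by their mean dye estimate of -0.132 (SD 0.0907). A single unusual wild-type culture was argued against by the excess from each wild-type hybridisation alone, 1.70 (SD 0.312) and 1.53 (SD 0.249), as far as these held separate cultures, which the labels do not tie to arrays. Cross-hybridisation between both runs cannot be told apart from 2 similar gene groups: their fold changes in ID order correlated at r = 0.856 in the best of 4 alignments (permutation p = 2e-04 from 10000 permutations, 95th percentile 0.562), and without probe sequences either could give this. A response to added AHL that exceeds that of wild-type may hold as a hypothesis, and the AHL level in wild-type cultures is not given in the sources used here.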
